A study of Mus musculus with 36 samples.

How the data were processed

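Per the labels' protocols, CD4 T cells were enriched magnetically and sorted as naive cells by flow cytometry from mice lacking TRIM28 in T cells and from WT littermates. Per the same protocols, stimulated cells were cultured for 72 h with plate-bound antibody to CD3 and soluble antibody to CD28. The labels name no cytokines for the lineages. Per the labels' protocols, total RNA was isolated on micro columns with DNase digestion, biotin-labeled and hybridized to mouse arrays read on an Affymetrix GeneTitan. Per the submitters' processing notes, the authors summarized the arrays to log2 values by RMA with the oligo package in R 3.1.0. The versions of oligo and RMA and the annotation were not stated there. The deposited log2 values were used as they were, with no further scaling. They ran from 2.05 to 13.5 over 41345 probe sets and 36 samples, and all columns of per-sample values were used.

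Probe sets were named by the accompanying probe table, which gave 1 symbol to 23521 probe sets, several symbols to 1814 and none to 16010. Probe sets with exactly 1 symbol were used, and of the 1082 genes with several of these the one with the highest mean was taken, which gave 22180 genes. Probe sets without a symbol were used in one alternative only. Of the genes, 13082 were tested, those above the table-wide median of 5.26 in at least 3 samples.

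Differences were tested with limma 3.58.1 in R 4.3.3, reading the files with the data.table package, version 1.17.8. A model with a mean for each of the 12 groups (24 residual degrees of freedom, 27.9 with the prior) was fitted to all 36 samples, and 17 comparisons were taken from it. The p-values from limma's moderated test were adjusted by the Benjamini-Hochberg method within each comparison. A gene was called changed at an adjusted p under 0.05. The comparisons were KO against WT in each condition and averaged over the 6, WT Th0 against naive, each polarized WT condition against Th0, and the differences of the KO effect for the same 5 pairs. Gene lists, 24 in number, were written from general knowledge, each tested with its members among the 13082 genes. The filter left out many markers of other cells, such that 4 of 20 germline genes, 3 of 15 NK and gamma-delta T cell genes and 1 of 11 erythroid genes were tested. They were tested with limma's camera at a preset correlation between genes of 0.01, with camera at an estimated correlation and with fry, and adjusted over the lists of a comparison. The counts of list members used the adjusted p over all genes, and where stated the adjusted p over the list alone.

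Genes were named by a rule. For the mean over the 6 conditions these were the 10 highest and 10 lowest changed genes with the same sign in all 6, in a comparison of 2 groups the 5 highest and 5 lowest whose 3 samples all lay beyond those of the other group, and in the differences the 3 highest and 3 lowest. To these came up to 4 changed members of each list and a fixed set read in every comparison (Trim28, Tbx21, Ifng, Gata3, Il4, Il13, Il17a, Il17f, Foxp3, Il2, Il10, Mki67 and Tgfb3). Sex-linked genes and uncharacterized or small RNA symbols were left out of the ranking. Lineage signatures were the 100 genes that rose most in each WT lineage against WT Th0, tested in KO against WT in the 3 other lineages, 12 tests in all.

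The comparisons, the model, the filter, the lists, the naming rule and the alternatives were fixed before the data were examined, apart from 4 alternatives that were chosen after the data had been seen. These were a term for the sex of the mouse by Xist, leaving out the KO Th0 and KO Th1 samples numbered 1 together, pairing Th0 with Th1 samples by replicate number within genotype, and the list of TRIM28 partners without Trim28, which had been written into it. The alternatives fixed beforehand were no filter, a stricter filter (above 6.95, the 70th percentile, in 3 samples), quantile normalization again, centering each sample on its median, cyclic loess, the mean of a gene's probe sets, and all probe sets named or not. They also held a trended and robust prior, array weights, a fit to only the groups compared, the replicate number as a fixed block, genotype and replicate number as a random block, each sample left out in turn, and signatures of 50 or 200 genes.

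The replicate number was checked for pairing by correlating the deviations of same-numbered samples from their group means. It was above 0.1 for all 3 numbers for WT Th1 with WT Th0 (0.39, 0.33 and 0.23), for WT Th2 with WT Th0 (0.25, 0.12 and 0.11) and for KO Th0 with KO Th1 (0.70, 0.60 and 0.51); the fit held no block.

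The steps were tested on simulated data, in which 200 genes were made to differ between KO and WT Th17 samples. Of those made to differ by a log2 change of 0.5, 36 of 67 were recovered (53.7%), of those by 1, 62 of 67 (92.5%), and of those by 2, all 66. There were 4 false calls among 12882 unchanged genes. The simulated noise was independent between genes and between samples, unlike the real values, so these rates need not hold for the real comparisons. Genotypes were also regrouped, over all 10 splits of 6 samples, or over 100 drawn splits within condition for the mean of the 6 and the differences. Neighborhood on the chromosome was compared with 10000 random gene sets. Raw array images and intensities were not used here, nor were probe sets with several symbols, and transcripts of repeats and endogenous retroviruses were not analysed here.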

Results

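Expression arrays were run on CD4 T cells from wild-type littermate mice (WT) and from mice whose T cells lack TRIM28 (KO), in 36 samples that form 12 groups of 3. TRIM28, also called KAP1, is a co-repressor that zinc-finger proteins with a KRAB domain bring to DNA, where it recruits the histone methyltransferase SETDB1. For each genotype, naive cells were profiled beside cells stimulated for 72 h through CD3 and CD28 in conditions named Th0 (stimulation without a named lineage), Th1, Th2, Th17 and Treg. The array values were log2 intensities whose sample medians lay between 5.18 and 5.35, and the mean correlation between the replicates of a group lay between 0.976 and 0.994. The number of arrays, 3 per group, limits the precision. A gene's change is given as its log2 fold change with its standard error in parentheses, from a limma fit to all 36 samples, and it passed at an adjusted p under 0.05 over 13082 genes. The labels do not say whether the samples of a group came from separate animals, so the p-values measure the spread between samples.

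Trim28 itself was lower in all KO samples. Its level lay between 9.21 and 9.99 in the 18 WT samples, at 7.86, 7.20 and 7.65 in the naive KO samples, and between 5.51 and 6.58 in the stimulated KO samples. The fall was 3.95-fold in naive cells, a change of -1.98 (0.16), and 14.3-fold in Th0, 13.5-fold in Th1, 10.9-fold in Th2, 11.1-fold in Th17 and 8.48-fold in Treg. Averaged over the 6 conditions it was 9.60-fold (-3.26, SE 0.07, adjusted p = 1e-24), and the difference of the KO effect between Th0 and naive cells also passed (-1.85, adjusted p = 7.6e-06).

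**Figure D1:**
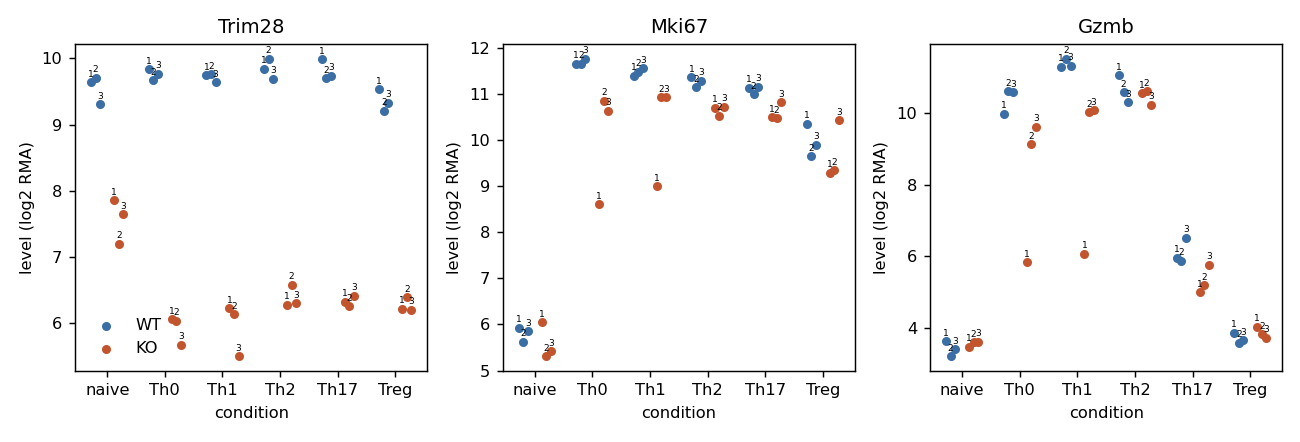
Levels (log2 RMA, vertical axis) of Trim28, Mki67 and Gzmb in each WT (blue) and KO (orange) sample by condition (horizontal axis), with replicate numbers beside the points. Trim28 was between 5.51 and 7.86 in KO and between 9.21 and 9.99 in WT samples, and the KO Th0 and KO Th1 samples numbered 1 lay apart in Mki67 (8.61 and 9.0) and Gzmb (5.84 and 6.07).

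Averaged over the 6 conditions, the comparison of KO with WT asked which genes TRIM28 loss moves on average, a mean that few conditions can carry. The rises and falls ranked here are those of characterized genes with the same sign in all 6 conditions. The 3 largest rises were in genes not known for a role in T cells. Pgpep1l, which encodes a pyroglutamyl peptidase-like protein, rose 19.7-fold (4.30, SE 0.10, adjusted p = 9.9e-23), the vomeronasal receptor gene Vmn2r96 9.73-fold (3.28, SE 0.15) and Myo5b, an unconventional myosin, 5.61-fold (2.49, SE 0.10). Prr5 (2.24), the neuronal calcium channel gene Cacna1b (2.20), Snai3 (1.90), Pld4 (1.86), Upk1b (1.80), Bmp7 (1.79) and Abca5 (1.79) followed. After Trim28, the largest falls were in Cpe (2.92-fold lower, -1.54, SE 0.09), Ptgfrn (-1.31), Stc2 (-1.23), Tube1 (-1.23) and Csn2 (-1.19). In all, 6073 genes changed, 2474 up and 3599 down, and 98 of them by at least 2-fold (53 up and 45 down).

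Tested in each condition on its own, 18 genes were higher in all 6, among them Pgpep1l, Vmn2r96, Myo5b, Bmp7, Trim24, Mbd1, Acadm and the piRNA-pathway helicase gene Tdrd9. A further 4 were lower in all 6 (Trim28, Cdh24, Marchf6 and Rnf43). Those not among the largest changes were picked after their values were seen. In exactly 1 condition 1678 genes were higher and 1741 lower. The genes raised in naive KO cells and in KO Treg cultures shared 39, where 2.12 would be shared by independent sets. Those raised in Th2 and Th17 shared 224 against 39.6, and those lowered in Th0 and Treg shared 77 against 64.3. KO Th0 and KO Th1 shared 1547 raised and 2155 lowered genes (374 and 608 for independent sets). The deviations of their samples from the group mean, however, correlated between samples of the same number (r across genes, which are not independent replicates, 0.70, 0.60 and 0.51), so these were not independent comparisons.

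**Figure D2:**
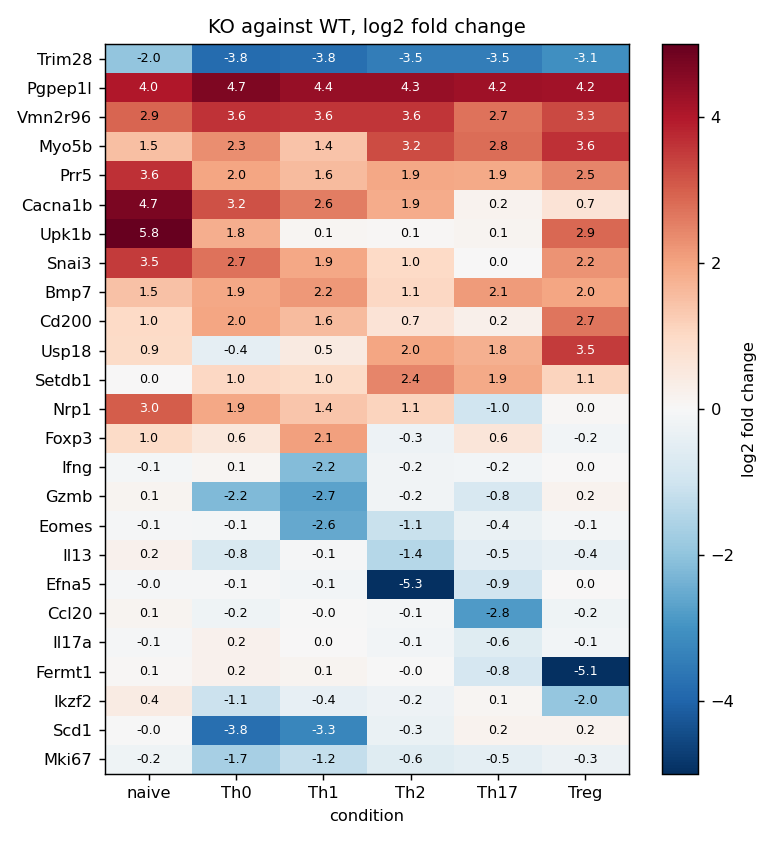
Log2 fold change of KO against WT (color and printed value) for 25 genes (vertical axis) in each of the 6 conditions (horizontal axis). Pgpep1l and Vmn2r96 were raised in every condition, whereas Efna5 had its large fall in Th2 (-5.30), Ccl20 in Th17 (-2.84) and Fermt1 in Treg (-5.10).

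Among genes linked to TRIM28, the mean over conditions gave a rise of Setdb1, the partner methyltransferase (1.24, SE 0.06, 2.36-fold), and of Trim24 (1.04, SE 0.04), and a fall of Uhrf1 (-1.05), an adaptor of DNA methylation maintenance. Uhrf1 rose 17.7-fold with stimulation in WT. It had -2.67 in KO Th0 and -2.12 in KO Th1, where the proliferation genes fell, so its fall was not shown to be separate from theirs. The list of 18 TRIM28 partner genes held Trim28 itself. Without it, a change made after the data were seen, 6 of 17 rose and 5 fell, with a median of -0.01 and a mean of 0.05. Camera did not call these 17 (adjusted p = 0.20) and fry called them up (8.4e-06). Of 289 tested zinc-finger protein genes (Zfp), the family that holds many TRIM28-recruiting repressors, 98 rose and 19 fell (92 and 18 adjusted over the list alone), led by Zfp53 (1.02), Zfp948 (0.86) and Zfp831 (0.74). The list moved up by camera (adjusted p = 1.7e-05, but 0.51 with an estimated correlation). More of its genes rose than fell under each of the 3 other scalings, with 66 up and 29 down when samples were centered on their medians. Of 17 imprinted genes 4 rose (Peg13 0.40) and 4 fell (Dlk1 -0.34), a split that became 3 up and 6 down under median centering and 4 up and 6 down after quantile normalization, and of the 4 germline genes that passed the filter 1 rose, Tdrd9 (1.01).

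The proliferation genes fell as a whole on the mean over the 6 conditions, carried by Th0 and Th1, 29 of 29 tested members over all genes and adjusted over the list alone. Their median was -0.74, with Bub1 (-1.19, SE 0.19), Birc5 (-1.09), Kif11 (-0.96) and Mki67 (-0.74) as examples (camera adjusted p = 2.6e-10; adjusted p = 0.51 with an estimated correlation). Of 17 glycolysis genes 13 fell and 1 rose (Slc16a3 -0.82, Hk2 -0.80; adjusted p = 2.8e-05, and 0.51 with an estimated correlation). Of 16 cholesterol synthesis genes 14 fell (Lss -0.57, Fdps -0.57; adjusted p = 9.6e-05, and 0.58 with an estimated correlation). Naive and quiescence genes moved the other way, with 15 of 20 up and 2 down (Pik3ip1 0.78, Btg2 0.53, Igfbp4 -0.79; adjusted p = 0.00013, and 0.51 with an estimated correlation). Of 27 interferon-stimulated genes 14 fell, such as Oas2 (-1.12) and Oasl2 (-1.07), while Usp18, which dampens interferon signaling, rose by 1.37 (list adjusted p = 0.046, and 0.83 with an estimated correlation). The KO Th0 and KO Th1 samples numbered 1 may carry part of these changes. They had far lower Mki67 (8.61 and 9.0) and Gzmb (5.84 and 6.07) than their replicates (Mki67 10.6 to 10.9, Gzmb 9.14 to 10.1). Without both samples 5512 genes changed over the 6 conditions, and at least 24 of the 29 proliferation genes stayed lower in each of Th0 and Th1.

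**Figure D3:**
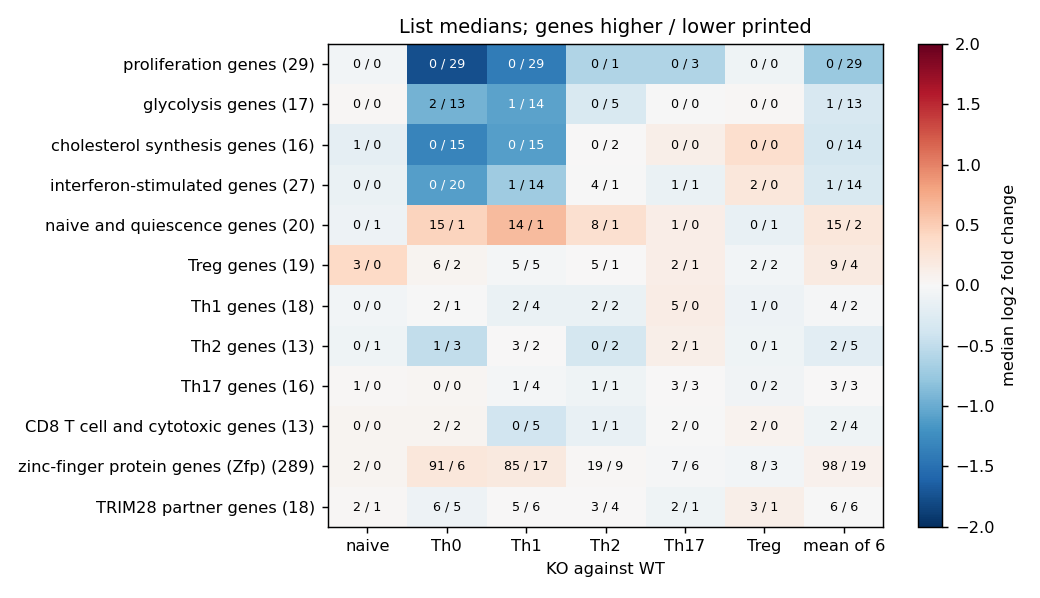
Median log2 fold change of KO against WT (color) of 12 gene lists (vertical axis, tested members in parentheses) in each condition and on average (horizontal axis), with the numbers of genes higher and lower printed. Proliferation, glycolysis and cholesterol synthesis genes lay furthest below 0 in Th0 and Th1 (proliferation medians -1.76 and -1.40); the median of the Zfp list changed sign with the scaling in Th2 and Th17, and the TRIM28 partner list shown holds Trim28.

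By camera, genes of the T cell lineages did not move as groups on average over the conditions. Of 19 Treg genes 9 rose and 4 fell, with Izumo1r (folate receptor 4) up by 1.24 (SE 0.08), Nrp1 (neuropilin-1) by 1.09, Gpr83 by 0.87 and Foxp3, the Treg master regulator, by 0.63 (SE 0.14, adjusted p = 0.00068). Of 18 Th1 genes 4 rose and 2 fell (Eomes -0.72, Hopx 0.44), and of 13 Th2 genes 2 rose and 5 fell (Gata3 0.29, Il4 -0.43, Il13 -0.49). Of 16 Th17 genes 3 rose and 3 fell (Maf -0.61, Cxcr5 0.58), and Tbx21, Ifng, Il17a and Il2 did not pass, although Il17a did without WT Th17 3 and Ifng without KO Th0 3 or KO Th1 3. Under median centering the Th17 split became 2 up and 5 down. Inhibitory receptor genes gave 5 up and 1 down of 10 (Cd200 1.36, Btla 0.80, Entpd1 -0.53), and TGF-beta pathway genes 8 up and 3 down of 18 (Tgfb3 0.96, Tgfbr2 0.41, Smad7 0.39, Pmepa1 -0.56). Activation and memory genes gave 1 up and 7 down of 23 (Slc7a5 -0.74, Irf8 -0.70, Tfrc -0.56). Of 17 p53 target genes 2 rose and 9 fell (Perp -0.84), and of 18 immediate early and heat shock genes 3 rose and 3 fell. Markers of other cells gave 2 up and 4 down of 13 for CD8 and cytotoxic genes (Prf1 0.50, Klrk1 -0.43). They gave 1 lower of 7 for B cell genes (H2-Ab1), and 1 up and 1 down of 7 for myeloid genes. In limma none of the 3 NK and gamma-delta T cell genes, the 1 erythroid gene and the 4 sex-linked genes passed, nor at an unadjusted p under 0.05. Camera called none of these lists. Fry called some, such as Treg up (adjusted p = 0.012), Th2 down (0.044) and activation and memory genes down (0.019).

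In naive cells the KO effect was narrow: 150 genes changed, 124 up and 26 down, and 64 of the raised genes by at least 2-fold. Trim28 itself fell less there than in stimulated cells (3.95-fold against 14.3-fold in Th0). The low count thus cannot be assigned to the naive state alone. Upk1b, a uroplakin of the bladder lining, rose 55.4-fold (5.79, SE 0.32, adjusted p = 2.1e-13), Cacna1b 26.2-fold (4.71, SE 0.20), Pgpep1l 16.1-fold, Prr5 12.5-fold and the transcription factor gene Snai3 11.3-fold; in each of these all 3 KO samples lay above all 3 WT samples. Beside Trim28, the largest falls were in the integrin gene Itgb3 (2.88-fold lower, -1.53, SE 0.19) and Myo10 (-1.08, SE 0.22). Nrp1 rose 8.14-fold (3.03, SE 0.29, adjusted p = 3.1e-08), Tdrd9 9.09-fold, Trim24 4.30-fold, Tgfb3 by 1.58, Cxcr5 by 1.42, Zfp781 by 1.26, Mvd by 1.22, Morc3 by 1.15 and Il2rb by 1.03.

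The Treg list stood higher in naive KO cells, with 3 of 19 genes up over all genes and 6 adjusted over the list alone, a median of 0.40 and a camera adjusted p of 2.3e-07 (adjusted p = 0.21 with an estimated correlation). The 3 were Nrp1, Il2ra (1.06, SE 0.24; not passed without WT naive 2, WT naive 3 or KO naive 2) and Tnfrsf18 (0.61; not passed without WT naive 2, WT naive 3 or KO naive 1). Foxp3 had 0.96 (SE 0.35, adjusted p = 0.34 over all genes and 0.035 over the list alone). The germline list was called because of Tdrd9 alone (adjusted p = 0.00071, and 0.015 with an estimated correlation). The Zfp list was called up as well, although 2 of its 289 members rose (adjusted p = 0.0018, and 0.68 with an estimated correlation). So were the 17 TRIM28 partners other than Trim28, of which 2 rose, Trim24 and Morc3 (adjusted p = 0.0014, and 0.24 with an estimated correlation). None of the proliferation genes passed in naive cells, and none did at an unadjusted p under 0.05 in limma. These genes were low in WT naive cells, with Mki67 at a mean of 5.80. Stimulation raised 28 of the 29 in WT, by a median log2 change of 4.26. They had little room to fall in naive cells, so this result cannot show whether TRIM28 loss spares them there. By Xist, KO naive 1, KO naive 2 and WT naive 1 came from females and the other naive samples, like all stimulated samples, from males. With a term for sex, chosen after the data were seen, 146 genes changed and 126 of the 150 were shared, and the median of the Treg list was 0.24 instead of 0.40, with 3 of its genes still up. Without KO naive 2 the count was 236, and a fit to the naive samples alone gave 90, without Il2ra, Il2rb and Tnfrsf18.

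In Th0, stimulated KO cells fell short of WT cells in several metabolic and growth programs. The fatty acid desaturase genes Fads2 and Scd1 were 15.3-fold (-3.94, SE 0.56) and 13.5-fold lower (-3.76, SE 0.48), the matricellular gene Ccn3 12.2-fold lower (-3.61, SE 0.23) and the antiviral gene Oasl2 11.9-fold lower (-3.57, SE 0.49). The KO Th0 samples were uneven in Oasl2 (standard deviation, SD, 1.66) and Fads2 (SD 1.16), and less so in Scd1 (0.42) and Ccn3 (0.36). Pgpep1l rose 25.5-fold, Vmn2r96 12.2-fold, Cacna1b 9.17-fold, Ankrd55 6.83-fold and Snai3 6.49-fold. All 29 proliferation genes fell, with a median of -1.76 (Bub1 -2.48, Birc5 -2.35, Aurkb -2.29; camera adjusted p = 5.6e-15, and 0.27 with an estimated correlation). Of 17 glycolysis genes 13 fell and 2 rose (Slc16a3 -1.74, Hk2 -1.56; adjusted p = 1.3e-06, and 0.24 with an estimated correlation). Of 16 cholesterol synthesis genes 15 fell (Fdps -2.20, Hmgcs1 -1.79; adjusted p = 1.5e-12, and 0.24 with an estimated correlation), and of 27 interferon-stimulated genes 20 fell (Oas2 -3.41, Ifit1 -2.37; adjusted p = 1.4e-09, and 0.24 with an estimated correlation). Naive and quiescence genes rose, 15 of 20 with 1 lower (Il7r 1.76, Pik3ip1 1.54, Actn1 1.37; adjusted p = 5.8e-05, and 0.24 with an estimated correlation). So did 91 Zfp genes against 6 that fell (Zfp53 1.69, Zfp948 1.51, Zfp831 1.39; adjusted p = 3.1e-07, and 0.24 with an estimated correlation). Adjusted over the list alone, 29 proliferation, 16 cholesterol synthesis and 22 interferon-stimulated genes were lower.

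Other groups in Th0 moved in part. Of 19 Treg genes 6 rose and 2 fell, among them Nrp1 (1.93) and Izumo1r (1.31), but 3 rose without KO Th0 1 and 3 without WT Th0 1, and their median of 0.06 turned to -0.005 under median centering. Slc7a5 (-1.85) and Tfrc (-1.11), a transporter of amino acids and the transferrin receptor, fell among the activation genes, and Cd200 (1.97) and Btla (0.97) rose among the inhibitory receptors. Of the TGF-beta pathway genes 7 rose and 2 fell (Smad7 0.95, Skil 0.91, Pmepa1 -1.49). Of the imprinted genes 5 rose (Airn 1.04, Peg13 0.84) although their median of 0.04 turned to -0.03 under median centering. Of the 17 TRIM28 partners other than Trim28 6 rose and 4 fell (Uhrf1 -2.67, Cbx5 -1.32, Dnmt1 -1.32). Stimulation raised Uhrf1 17.7-fold, Cbx5 5.44-fold and Dnmt1 2.23-fold in WT, so these falls were not shown to be separate from the lower growth genes. Mki67 had -1.66 and Gzmb -2.20, and both lost their call without KO Th0 1 or with the Th0 samples alone. In all 4765 genes changed, 2199 up and 2566 down, and 564 of the lowered and 189 of the raised by at least 2-fold. Without the KO Th0 and KO Th1 samples numbered 1, an alternative added after the data were seen, 3777 genes changed. The proliferation count then stayed at 29 (median -1.25), the interferon count went to 16, the quiescence count to 13 and the raised Zfp genes to 66.

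In Th1, the KO cells had less of some cytotoxic and Th1 effector genes. Eomes, a T-box factor of effector cells, fell 5.87-fold (-2.55, SE 0.26, adjusted p = 3.5e-08), and Ifng, the signature cytokine of Th1 cells, 4.52-fold (-2.18, SE 0.51, adjusted p = 0.0011). Ifng was uneven between the KO samples, at 6.35, 8.02 and 10.2 against 9.84 to 10.7 in WT, and in a fit to the Th1 samples alone it did not pass. Tbx21, which drives the lineage, had -0.52 and did not pass (adjusted p = 0.084), but did without WT Th1 1 or KO Th1 3, under median centering and with the replicate block. Hopx fell (-0.85) and Cxcr3 rose (0.85), and in all 2 of 18 Th1 genes were higher and 4 lower. The interferon-inducible gene Ifi204 was 13.8-fold lower (-3.79, SE 0.45), Scd1 9.61-fold and the Ets factor gene Etv5 7.39-fold lower. The KO Th1 samples were uneven in Ifi204 (SD 1.40) and Scd1 (SD 1.89), and less so in Etv5 (SD 0.33). Gzmb had -2.66, with its call lost without KO Th1 1 or with the Th1 samples alone. Besides Pgpep1l (20.7-fold) and Vmn2r96 (11.9-fold), the largest rises were in Cd24a (7.53-fold), Rflnb (6.75-fold) and Cacna1b (5.87-fold). Foxp3 was 4.15-fold higher (2.05, SE 0.35, adjusted p = 3.9e-05), with Nrp1 (1.39), Izumo1r (1.33), Tgfb3 (1.26), Gata3 (0.71) and Il4ra (0.60) also up. Il10 (-1.83), Il24 (-1.89), Klrk1 (-2.28), Klrc1 (-1.16) and H2-Ab1 (-1.65) were lower.

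The growth and metabolic groups fell in Th1 too. All 29 proliferation genes were lower, with a median of -1.40 (camera adjusted p = 6.1e-09, and 0.46 with an estimated correlation). Of 17 glycolysis genes 14 fell and 1 rose (Slc16a3 -2.01, Hk2 -1.92; 1.4e-07, and 0.19), and of 16 cholesterol synthesis genes 15 fell (Fdps -1.58, Hmgcs1 -1.49; 7.4e-09, and 0.32). Of 27 interferon-stimulated genes 14 fell and 1 rose (Oasl2 -2.25, Mx2 -1.44; 0.022, and 0.87). Quiescence genes rose, 14 of 20 with 1 down (Actn1 1.90, Pik3ip1 1.72, Btg2 1.26, Bach2 1.23; 2.8e-07, and 0.19). So did 9 of 18 TGF-beta pathway genes with 3 down (Smad7 1.18, Tgfbr2 0.90; 0.035, and 0.32) and 85 Zfp genes against 17 (Zfp831 1.66, Zfp2 1.62; 3.2e-06, and 0.32). KO Th1 1 carried part of this. Without it 17 proliferation genes were lower, 52 Zfp genes were higher and 8 lower, and 3 CD8 and cytotoxic genes were lower instead of 5. Likewise 3 activation genes were lower instead of 6, and 4 Treg genes were higher with 0 lower, by limma, instead of 5 and 5. The Treg split was 4 and 3 without WT Th1 2 or WT Th1 3, and the Zfp split 62 and 10 without WT Th1 2. Without the samples numbered 1 of KO Th0 and KO Th1, the proliferation count was 24 (median -0.87) and the count of all changed genes 3881, against 5328 (2227 up and 3101 down) with all samples.

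In Th2, single genes moved far. Efna5, an ephrin ligand, was 39.3-fold lower in KO (-5.30, SE 0.14, adjusted p = 1.2e-21), Tcaf3 30.9-fold lower (-4.95, SE 0.18), the enkephalin precursor gene Penk 18.2-fold (-4.18, SE 0.97), the neurotensin gene Nts 18.1-fold (-4.18, SE 0.14) and Akr1c18 16.5-fold lower (-4.05, SE 0.31). Ly6g, a surface marker of neutrophils, was 22.1-fold higher (4.47, SE 0.37), Pgpep1l 20.2-fold, Vmn2r96 11.9-fold, Mpzl2 10.8-fold and Myo5b 9.52-fold higher. Of 13 Th2 genes 2 fell, Il13 2.66-fold (-1.41, SE 0.32, adjusted p = 0.0024) and Il9, which did not pass without KO Th2 1, KO Th2 2 or WT Th2 3, while Il4 (-0.35, adjusted p = 0.24; passed with array weights) and Gata3 (0.10) did not pass. Setdb1 rose 5.43-fold (2.44), Usp18 by 1.97, Mx1 by 1.63, Gzma by 1.91, Izumo1r by 1.51, Dapl1 by 1.40, Zfp53 by 1.35 and Zfp831 by 1.18. Of the 7 myeloid genes 1 rose, Adgre1 (1.10), and 0 fell. Hk2 (-1.19), Slc2a3 (-0.95), Eomes (-1.13), Igfbp4 (-1.12), Lss (-0.78) and Maf (-0.66) fell.

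Changes of whole groups were smaller in Th2. Naive and quiescence genes gave 8 up and 1 down of 20 (camera adjusted p = 0.0058, and 0.92 with an estimated correlation), with 4 up without KO Th2 1, 3 without KO Th2 2, 5 without WT Th2 1 and 4 without WT Th2 3. Of the glycolysis genes 5 of 17 fell (0.0035, and 0.92), 2 without WT Th2 2 and 3 without WT Th2 3, and of the proliferation genes 1 of 29, E2f1, which did not pass without KO Th2 2 (median -0.60; 0.0035, and 0.92). Among interferon-stimulated genes 4 rose and 1 fell. The Zfp genes gave 19 up and 9 down (20 and 5 without WT Th2 2), and their median of 0.02 turned to -0.03 when samples were centered on their medians. In all 2144 genes changed, 982 up and 1162 down; a fit to the Th2 samples alone gave 1186, and array weights gave 3368.

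In Th17, the cytokines that define the lineage moved little. Il17f had -0.30 (SE 0.23, adjusted p = 0.51) and Il17a -0.62 (SE 0.19, adjusted p = 0.041), which did not pass without WT Th17 1, WT Th17 2 or KO Th17 3, nor with array weights, no filter, quantile normalization again or the Th17 samples alone; in the last of these Il23r was lost too. Around them, the chemokine gene Ccl20 fell 7.15-fold (-2.84, SE 0.23, adjusted p = 7e-10) and Maf 2.32-fold (-1.21), while the interleukin-1 receptor gene Il1r1 rose 5.92-fold (2.57, SE 0.20) and Il23r 2.19-fold (1.13), which left 3 of 16 Th17 genes up and 3 down. Outside the lineage, the myeloid inhibitory receptor gene Clec12a rose 22.4-fold (4.49, SE 0.21), the meiosis gene M1ap 21.7-fold, Pgpep1l 18.8-fold, the choline transporter-like gene Slc44a5 12.7-fold and Ldhd 9.18-fold. Akr1c18 was 35.2-fold lower (-5.14, SE 0.31), Ccn3 13.4-fold, Abi3bp 8.84-fold and Kynu 7.57-fold lower.

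Of 18 Th1 genes 5 were higher in KO Th17, among them Il18rap (1.45) and Hopx (1.18). Camera called the list (adjusted p = 0.019, and 0.86 with an estimated correlation). Without KO Th17 1, KO Th17 3 or WT Th17 1 only 3 passed, and without KO Th17 2 or WT Th17 3 only 2. Proliferation genes lay lower as a list (median -0.61, 3 of 29 passing; 9.8e-05, and 0.86). Il4 (-1.56), Ifih1 (-1.33), Zfp750 (-1.33), Zfp9 (-1.24) and Tgfbr1 (-0.91) fell, and Csf2 (1.51), Tigit (1.63), Usp18 (1.77), Setdb1 (1.88), Tgfb3 (1.35), Gzma (1.16) and Itgam (0.77) rose. None of the glycolysis genes passed in limma, nor at an unadjusted p under 0.05. None of the cholesterol synthesis genes passed either, with 1 at that unadjusted level in limma. The Zfp list gave 7 up and 6 down, which turned to 5 and 8 when samples were centered on their medians. It was 4 and 3 without KO Th17 1, 4 and 5 without KO Th17 3 or WT Th17 2, and 3 and 4 without WT Th17 1 or WT Th17 3. In all 1074 genes changed, 527 up and 547 down. The count was 677 without WT Th17 1, 709 without KO Th17 1 and 622 without WT Th17 3, and 2807 with array weights.

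In Treg, Foxp3 stood at the level of WT (-0.15, SE 0.35, adjusted p = 0.91) while other Treg genes went apart. Gpr83 rose 5.55-fold (2.47, SE 0.38) and Izumo1r 3.76-fold (1.91, SE 0.20), and Ikzf2, which encodes the Treg factor Helios, fell 3.87-fold (-1.95, SE 0.29). In all 2 of 19 Treg genes were higher and 2 lower. The adhesion gene Fermt1 was 34.2-fold lower in KO (-5.10, SE 0.31, adjusted p = 1.2e-12), the potassium channel subunit gene Abcc8 6.52-fold and Acsl6 6.04-fold lower. Pcp4 was 23.4-fold higher (4.55, SE 0.15), with Pgpep1l 18.1-fold, Myo5b 12.4-fold, Usp18 11.2-fold and Vmn2r96 9.97-fold. Cd200 rose 6.43-fold (2.68) and Btla 3.22-fold (1.69). Maf (-1.43), Rora (-0.96), Icos (-0.85) and Skil (-0.78) fell, and Itgam (1.72), Prf1 (1.67), Zfp983 (1.19), Setdb1 (1.10) and Morc3 (0.78) rose.

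None of the proliferation genes passed in KO Treg by limma, nor at an unadjusted p under 0.05; KO Treg 3 had an Mki67 level of 10.4 against 9.30 and 9.35 in its replicates. Camera called 5 lists up. The cholesterol synthesis genes were 1 of them (adjusted p = 5.6e-05, and 0.50 with an estimated correlation), although none passed in limma. Of these genes 6 were higher and 1 lower at an unadjusted p under 0.05, and 2 were higher and 1 lower adjusted over the list alone. Interferon-stimulated genes had 2 of 27 up (3e-05, and 0.50) and TRIM28 partners other than Trim28 3 of 17 up (2.6e-05, and 0.092; with Trim28 0.005, and 0.48). The other calls were for CD8 and cytotoxic genes (2 of 13 up; 0.042, and 0.50) and myeloid genes (2 of 7 up, with Itgam the larger; 0.0024, and 0.13). In all 552 genes changed, 224 up and 328 down. That count was sensitive to single libraries, at 945 without WT Treg 1, 364 without KO Treg 2, 343 without WT Treg 2 and 341 without WT Treg 3; a fit to the Treg samples alone gave 215, without Rora, and array weights gave 2834.

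The KO effect was then compared between conditions, to ask whether it depended on the state of the cell. A gene near the array floor in a WT condition could not fall there, so its difference can follow where WT cells expressed it. Trim28 fell less in naive KO cells, so the difference from naive cells does not separate cell state from the extent of Trim28 loss. From naive cells to Th0, 2418 genes had a different KO effect, 1055 more positive and 1363 more negative in Th0 (1513 without KO Th0 1). Upk1b (-3.98, SE 0.46), raised far more in naive cells, Fads2 (-3.95) and Scd1 (-3.75) led on one side, and Pde2a (2.80, SE 0.55) and St8sia6 (2.70) on the other. The proliferation (24 of 29 negative, 13 without KO Th0 1), glycolysis (13 of 17) and cholesterol synthesis genes (14 of 16) had a more negative KO effect in Th0. So did 17 of 27 interferon-stimulated genes, which were 7 without KO Th0 1 and 11 without KO naive 1, WT naive 1 or WT naive 2. Camera's adjusted p for these was 1e-14, 2.9e-07, 3.1e-12 and 1.1e-08, and with an estimated correlation the adjusted p = 0.28 for the first and the last and 0.20 for the others. Quiescence genes went the other way in Th0, with 14 of 20 more positive and 1 more negative (Il7r 2.01, Actn1 1.34; adjusted p = 4.7e-07, and 0.20 with an estimated correlation). These were 9 without WT Th0 2 or WT naive 1 and 7 without KO Th0 1. With a term for sex 2516 genes differed.

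Between Th1 and Th0 the KO effect differed in 77 genes, 18 more positive and 59 more negative in Th1. The count was 51 without KO Th0 1, 45 without WT Th0 3, 37 without WT Th1 3 and 34 without the samples numbered 1 of both KO groups. It was 19 in a fit to these groups alone, which lost Klrk1, Serpinb5, B4galnt4, Ccr8 and Ifi204, and 164 with array weights. Eomes (-2.46, SE 0.36, adjusted p = 0.00044), Klrk1 (-2.19, SE 0.33), Serpinb5 (-2.35) and Hopx (-1.62) had the more negative effect in Th1, and Cpe (2.20, SE 0.31) and B4galnt4 (1.94) the more positive. In WT Th0, Klrk1 (3.42), Serpinb5 (3.50) and Eomes (5.23) lay below the filter threshold of 5.26 and had little room to fall, unlike Hopx (6.96). Ifng differed by -2.28 (SE 0.72) and did not pass (adjusted p = 0.22), though it did without KO Th1 3. As replicate numbers followed each other between Th0 and Th1, a fit that paired these samples by number within genotype was added after the data were seen; it gave 97 genes, and in it the difference of Ifng passed (SE 0.37, adjusted p = 0.0013). CD8 and cytotoxic genes were more negative in Th1 as a list, 3 of 13 (camera adjusted p = 7.4e-06, and 0.04 with an estimated correlation; fry 0.0062). Other lists were called up with few or no members passing. Interferon-stimulated genes had a median of 0.50 (adjusted p = 1.4e-10, and 0.29 with an estimated correlation; 0 of 27 passed in limma and 8 were higher at an unadjusted p under 0.05). Th2 genes had 2 of 13 more positive (0.0042, and 0.29). Of the proliferation (0.0011, and 0.72), quiescence (0.0068, and 0.71) and cholesterol synthesis genes (0.031, and 0.72) none passed in limma; at an unadjusted p under 0.05 none of the first, 2 higher and 1 lower of the next and 1 lower of the last did.

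Against Th0, the KO effect on growth genes was less negative in Th2, Th17 and Treg. For the cholesterol synthesis genes 14 of 16 differed in Th2, 15 in Th17 and 15 in Treg, with medians of 1.25, 1.31 and 1.65 (camera adjusted p = 2.1e-15, 2.4e-16 and 2.9e-15, and 0.17, 0.18 and 0.18 with an estimated correlation). Interferon-stimulated genes gave 15, 16 and 21 of 27 (10 in Th17 without KO Th0 1) and proliferation genes 7, 7 and 23 of 29. The latter counts rested on single samples. Without KO Th0 1 they were 2, 2 and 14, and without KO Th0 2 the first pair were 18 and 22. In Th17 that count was 4 without any one of KO Th17 1, KO Th17 2, KO Th17 3, WT Th0 2, WT Th0 3 or WT Th17 2, and in Th2 it was 4 without KO Th2 3. The adjusted p with an estimated correlation was 0.17, 0.29 and 0.18 for the interferon list and 0.51, 0.51 and 0.27 for the proliferation list. Room to fall differed: in WT Treg Oas2 and Oasl2 stood at 5.09 and 5.33, against 9.93 and 10.1 in WT Th0. Bub1 in WT Treg (7.48) stood near its KO Th0 level (7.57). The interferon counts and the Treg counts therefore do not by themselves show a milder KO effect. No cholesterol synthesis gene was lower in WT Th2 or Th17 than in WT Th0.

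Single genes passed this test too, many of which had changed in more than one condition. In Th2 these were Efna5 (-5.22, SE 0.19), Tcaf3 (-4.96), Nts (-4.26), Ly6g (4.13, SE 0.53) and Setdb1 (1.40). In Th17 they were Clec12a (4.39, SE 0.30), M1ap (4.17), Akr1c18 (-3.12), Nrp1 (-2.92), Ccl20 (-2.63), Il1r1 (2.51) and Il4 (-1.04), and in Treg Fermt1 (-5.31, SE 0.44), Pcp4 (4.53, SE 0.21), Usp18 (3.93), Gpr83 (2.13), Maf (-1.58) and Itgam (1.85). Of the falls, Efna5 (4.12) and Fermt1 (3.79) lay below the filter threshold in WT Th0 and had little room to fall there. The number of genes with a different KO effect was 1333 in Th2 (727 without KO Th0 1, 864 without WT Th2 2), 2044 in Th17 (1277 without KO Th0 1) and 3529 in Treg. With array weights these counts were 2904, 3491 and 5326, and a fit to the groups compared gave 848 in Th2.

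The WT samples alone showed what stimulation and each condition did. From naive to Th0, 7006 genes changed, 4085 up and 2921 down, with 11898 over all probe sets, named or not, and 6894 with a term for sex, since WT naive 1 was female and all stimulated samples male. The signaling inhibitor gene Socs2 rose 141-fold (7.14, SE 0.28), Gzmb 127-fold, Lilrb4a 82.6-fold, Mki67 59.4-fold, Il2ra 30.6-fold and Foxp3 11.9-fold. Slc16a5 (53.1-fold lower), Dtx1 (20.8-fold), Apol8 (19.9-fold) and Rgs2 (14.9-fold) fell. Of the proliferation genes 28 of 29 rose (camera adjusted p = 1.1e-15, and 0.21 with an estimated correlation) and of the cholesterol synthesis genes 16 of 16 (5.2e-09, and 0.21). Glycolysis genes gave 15 of 17 up with 1 down (2.9e-06, and 0.21), Treg genes 15 of 19 up with 1 down (2.9e-06, and 0.21) and quiescence genes 17 of 20 down with 1 up (3e-07, and 0.21). Of the p53 target genes 13 of 17 rose with 1 down (Cdkn1a 4.54; 0.00076, and 0.53). Of the immediate early and heat shock genes 12 of 18 fell with 2 up (Fos -3.60, Egr1 -2.99; 0.001, and 0.21). The median of all genes was 0.12 higher here when samples were centered on their medians.

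The Th1, Th2 and Th17 conditions each raised their own lineage genes in WT cells. In Th1 against Th0, 1417 genes changed (711 up and 706 down; 2830 with array weights). Ly6a2 (48.6-fold), Ifi204 (33.5-fold), Ifng (24.9-fold, 4.64, SE 0.51) and Tbx21 (17.2-fold) rose, and Foxp3 was 6.07-fold and Ifngr2 5.07-fold lower. Of 18 Th1 genes 15 rose (camera adjusted p = 4.4e-28, and 5.4e-05 with an estimated correlation). The replicate numbers followed each other here (correlations of 0.39, 0.33 and 0.23 between the deviations of same-numbered samples, and 0.25, 0.12 and 0.11 in Th2). With the replicate number as a block 1496 genes changed in Th1 and 5354 in Th2. In Th2 against Th0, 5247 genes changed, with Adamtsl3 112-fold, Tnfrsf8 109-fold, Il24 101-fold, Il13 17.5-fold, Il4 12.7-fold and Gata3 3.58-fold higher and Foxp3 30.3-fold lower. Of 13 Th2 genes 10 rose (5.2e-11, and 0.0014). In Th17, 5119 changed, with Il17f 124-fold, Timp1 98.5-fold, Il21 74.0-fold, Il23r 51.0-fold and Il17a 23.1-fold higher. All 16 Th17 genes rose (4.9e-18, and 0.00028).

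In WT Treg against Th0, 5442 genes changed, with Fermt1 53.5-fold, Itgae 51.6-fold and Glp1r 21.6-fold higher and Gzmb 104-fold and Usp18 46.7-fold lower. Foxp3, already raised in Th0, was 2.45-fold higher (1.29, SE 0.35, adjusted p = 0.0038), and Nrp1 rose by 3.09, Nt5e by 2.39 and Ikzf4 by 1.88. In all 8 of 19 Treg genes were up and 4 down (2 down without WT Th0 2, WT Th0 3 or WT Treg 3; camera adjusted p = 0.036, and 0.57 with an estimated correlation). All 29 proliferation genes (median -2.06), 15 of 16 cholesterol synthesis genes and 13 of 17 glycolysis genes were lower than in WT Th0 (3.8e-13, 1.6e-10 and 2.3e-08; adjusted p = 0.36, 0.18 and 0.068 with an estimated correlation). Interferon-stimulated genes were lower in WT Th2 (24 of 27), Th17 (24) and Treg (25) than in Th0, whereas glycolysis genes were higher in Th1 (10 of 17), Th2 (15) and Th17 (14). Of the CD8 and cytotoxic genes 8 of 13 were higher in WT Th1 than in Th0, among them Klrk1 (2.88) and Nkg7 (2.52) (camera adjusted p = 1.1e-11, and 0.00042 with an estimated correlation). TGF-beta pathway genes rose in WT Treg, 11 of 18 with 2 down (Skil 2.49, Smad7 1.88; 2.1e-05, and 0.053), as they did in Th17, 10 with 2 down (Tgfb3 2.84; 0.0063, and 0.15), and Th2, 8 with 2 down (0.015, and 0.24). Of the Zfp genes 83 rose and 14 fell in WT Treg (0.00025, and 0.39).

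Last, the 100 genes that rose most in each WT lineage against WT Th0 were followed in KO cells of the other lineages. Camera called 4 of 12 such tests, and none with an estimated correlation. Over all 13082 genes, 2227 were higher and 3101 lower in KO Th1, and 527 and 547 in KO Th17. A call does not by itself show that a lineage program leaked. In KO Th1 cells the Treg signature was higher (32 genes up and 8 down; adjusted p = 0.00081, and 0.71 with an estimated correlation; fry 0.00069). The Th2 signature was lower there (3 up and 38 down; adjusted p = 0.0012, and 0.71; fry 0.00063), and so was the Th17 signature (3 up and 36 down; adjusted p = 0.00081, and 0.71; fry 0.0029). In KO Th17 cells the Th1 signature was higher (15 up and 5 down; adjusted p = 0.00081, and 0.71; fry 0.18).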

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

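For the results of this part, the splits and the stimulation and neighbor tests were set before their results were seen, and the tests of the samples numbered 1, of the scaling, of sex and of Treg cells were chosen after.

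The first pattern was the KO effect that differed between Th0 and naive cells in 2418 genes, between Th1 and Th0 in 77, between Th2 and Th0 in 1333, between Th17 and Th0 in 2044 and between Treg and Th0 in 3529. Of 100 drawn splits of genotype within condition, the real one among them, 8, 15, 9, 8 and 2 called as many genes, with 3467, 6875, 5290, 3567 and 3631 in the highest other split. Of these, 7, 13, 8, 7 and 1 kept the genotype whole in a condition and so carried the KO effect itself; apart from them the highest counts were 23, 212, 15, 3 and 421, and only for Th1 against Th0 did another split reach the real count. For Treg, 2 of 100 lay under the 5 in 100 set beforehand, against a chance division if the samples are independent between conditions. By that bar the other differences, at 8, 15, 9 and 8 of 100, met the prediction for a chance division. The bar did not provide for leaving out the splits that kept the genotype whole. For Th1 against Th0 the 77 genes could rest on single samples, with 34 left without the samples numbered 1. Some genes had little room to fall in WT Th0 (Efna5 4.12, Fermt1 3.79, Ifi204 3.90), so their difference can follow WT expression.

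The second pattern was the lower proliferation list in KO Th0 and KO Th1, with the differences that follow from it. The samples numbered 1 as the whole cause went against the test, with 24 of 29 genes still lower in the weaker of both conditions (17 in Th1 with KO Th1 1 alone left out), and so did scaling, with a median of -1.37 in the scaling nearest to 0. A stimulation response that went less far in the KO cultures may be a candidate explanation: 85.1% of the genes that stimulation raised in WT were lower in KO Th1 without its sample numbered 1. These raised genes still held growth genes outside the proliferation list, so the test was not independent of the pattern. Whether TRIM28 loss slowed the response or the cultures differed in timing or cell number is a hypothesis this test does not separate.

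The third pattern was the raised genes. Of the 53 genes raised at least 2-fold over the 6 conditions, 0 were among the 50 tested genes nearest to Trim28, against genes linked to the targeted gene as an explanation. A next tested neighbor that rose, by however little, stood beside 30 of them, against 17 in the median of the random gene sets. Neighbors whose symbols differed only in the ending number were not counted. The excess could come from local spread to neighboring genes, but the count does not show what made neighbors rise together.

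For Th0 against naive the differing genes were Pde2a (2.80), St8sia6 (2.70), Sidt1 (2.48), Upk1b (-3.98), Fads2 (-3.95), Scd1 (-3.75) and Trim28 (-1.85), whose naive KO samples kept more signal. The list medians for this difference were 0.62 for quiescence, -0.42 for activation and memory, -1.68 for proliferation, -0.84 for glycolysis, -1.13 for cholesterol synthesis, -1.20 for interferon-stimulated, 0.19 for Zfp and -0.25 for TRIM28 partner genes. With an estimated correlation their adjusted p lay between 0.20 and 0.41. The partner list held Trim28, and without it camera did not call it (median -0.20, adjusted p = 0.11). For Th1 against Th0 they were Cpe (2.20), Ccr8 (2.03), B4galnt4 (1.94), Ifi204 (-3.12), Eomes (-2.46) and Serpinb5 (-2.35). Of these Ccr8 did not pass in 7 of the fits with 1 library left out, and Ifi204 not without the samples numbered 1. In a fit to these groups alone Ccr8, Ifi204, B4galnt4 and Serpinb5 did not pass. The CD8 and cytotoxic list had a median of -0.46 (adjusted p = 0.04 with an estimated correlation).

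For Th2 against Th0 the genes were Ly6g (4.13), Oasl2 (3.68), Fads2 (3.56), Efna5 (-5.22), Tcaf3 (-4.96) and Nts (-4.26). The list medians were 1.21 for proliferation, 0.45 for glycolysis, 1.25 for cholesterol synthesis, 1.22 for interferon-stimulated, -0.24 for imprinted and -0.18 for Zfp genes (adjusted p from 0.17 to 0.51 with an estimated correlation). For Th17 against Th0 they were Clec12a (4.39), M1ap (4.17), Fads2 (4.03), Akr1c18 (-3.12), Cacna1b (-3.02), Nrp1 (-2.92), Il4 (-1.04) and Il17a (-0.84, not passed in 6 of the fits with 1 library left out, with array weights, in a fit to these groups alone or without both samples numbered 1). The medians were -0.34 for quiescence, 1.23 for proliferation, 0.96 for glycolysis, 1.31 for cholesterol synthesis, 1.25 for interferon-stimulated and -0.27 for Zfp genes (0.18 to 0.51). For Treg against Th0 they were Pcp4 (4.53), Scd1 (3.95), Usp18 (3.93), Fermt1 (-5.31), St8sia6 (-3.31), Abcc8 (-2.75), Trim28 (0.75) and Gata3 (-0.67, not passed in 7 of those fits, with no filter, quantile normalization again, cyclic loess or these groups alone, or without both samples numbered 1). The medians were -0.71 for quiescence, 1.64 for proliferation, 0.91 for glycolysis, 1.65 for cholesterol synthesis, 1.47 for interferon-stimulated and -0.25 for Zfp genes (0.18 to 0.27).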

How the results depend on the processing

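Of the 17 counts of changed genes, these moved by more than 1.5-fold under another setting; the cause was not tested. With array weights more genes changed: 3368 in KO Th2, 2807 in KO Th17, 2834 in KO Treg, 2830 in WT Th1 against Th0, and 164, 2904, 3491 and 5326 in the differences of the KO effect for Th1, Th2, Th17 and Treg against Th0. With only the groups compared, which leaves fewer degrees of freedom, fewer did: 90 in naive, 1186 in Th2, 215 in Treg, and 19 and 848 in the differences for Th1 and Th2; the mean over the 6 conditions has no such value because all groups are in it. All probe sets, named or not, gave 11898 in WT Th0 against naive and a median of all genes 0.14 lower. With the KO Th0 and KO Th1 samples numbered 1 both left out, the difference for Th1 was 34. Leaving out 1 sample, with the spread pooled by limma over the other groups, gave 106 to 236 in naive, 622 to 1072 in Th17, 341 to 945 in Treg, and 1513 to 2509, 37 to 96, 727 to 1669 and 1277 to 2385 in the differences for Th0 against naive and for Th1, Th2 and Th17 against Th0. The replicate block moved no count by that much (1496 in WT Th1 against Th0 with the block). Camera calls over all comparisons went from 112 gene lists to 8 with an estimated correlation, and lineage signatures from 4 to 0. Median centering moved the split of higher and lower genes to 1656 and 3000 in Th0, 1610 and 3825 in Th1, 766 and 1505 in Th2, 1714 and 4563 in the mean of the 6, 5064 and 2116 in WT Th0 against naive, and 772 and 1546 in its difference of the KO effect; cyclic loess gave 290 and 266 in Treg, quantile normalization 828 and 516 in WT Th1 against Th0, and all probe sets 4237 and 3750 in Th1 and 5197 and 6701 in WT Th0 against naive. No named gene turned direction. The 3 arrays per group limit the precision.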

Other observations

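In this part too, the tests of sex, Treg cells, scaling and the samples numbered 1 were chosen after the results were seen, and the splits, the stimulation test and the neighbor tests were set before. Among raised genes picked after their values were seen, several lay next to each other and rose together over the 6 conditions. Mbd1 (1.35), Cfap53 (1.13) and Myo5b (2.49) were such neighbors, as were Bmp7 (1.79) and Spo11 (0.94), Cd200 (1.36) and Btla (0.80), Izumo1r (1.24) and Gpr83 (0.87), Tmie (1.11) and Als2cl (0.93), and Nars2 (1.05) and Tenm4 (0.88).

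Of the 53 genes raised at least 2-fold, 30 had a raised next tested gene on either side, however small its rise. Neighbors whose symbols differed only in the ending number were not counted. Many of the counted neighbors rose far less than those pairs, such as Rtl6 (0.37) beside Prr5 and Slc41a2 (0.18) beside Chst11. The 30 compare with 17 in the median and 23 in the 95th percentile of 10000 random gene sets, which met the prediction for a local spread to neighboring genes. Raised neighbors such as Mbd1 and Cfap53 counted each other, and lowered genes were not tested alike. The count therefore does not show what made neighbors rise together. Genes linked to the targeted gene are an unlikely source, since 0 of the 53 were among the 50 genes nearest to Trim28; 24 of those 50 changed over the 6 conditions, close to the 46.4% of all tested genes. One hypothesis is that TRIM28 holds down regulatory elements, repeats among them, whose release reaches more than one gene; no repeat transcripts were analysed here, and chromatin maps of TRIM28 and of its histone mark would test it.

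The stimulation programs give a reading of the lower growth genes. Outside the proliferation list, stimulation raised 1201 genes at least 2-fold in WT and lowered 551. Without the KO Th1 sample numbered 1, 85.1% of the raised genes were lower in KO Th1 (median -0.57). Of the lowered genes 76.6% were higher (median 0.33). This met the prediction for a stimulation response that went less far. The raised genes still held growth genes outside that list, such as Tpi1 (-1.31 in KO Th1) and Fdps (-1.58). The test thus cannot separate a weaker response from the lower growth genes it was to explain. With all samples the shares were 88.0% and 79.9%, with medians of -0.73 and 0.41, against -0.03 over all genes in KO Th1. The samples numbered 1 are an unlikely sole cause, with 24 genes of the list lower without them and 17 in Th1 without KO Th1 1 alone, and so is the scaling, with a median of -1.37 at its nearest to 0. A time course with cell counts would separate a slower response from one that ended early.

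The naive KO samples had Foxp3 levels of 8.08, 8.89 and 7.88 against 7.88, 7.18 and 6.92 in WT, and 14 of the 18 Treg genes other than Nrp1 lay above 0. More Treg cells among the naive KO cells and a raised expression in each cell could each give this, and they cannot be told apart here. Per the labels the cells had been sorted as naive, a gate that would remove many Treg cells; sorting by a Foxp3 reporter would tell them apart. Sex is an unlikely cause of the naive changes as a whole, since 126 of the 150 genes stayed with a term for it, but the median of the Treg list went from 0.40 to 0.24 with that term. Foxp3 went from 0.96 to 0.72, so sex may carry part of the higher Treg genes.

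The splits of samples set bounds on the counts. For the mean over the 6 conditions, 1 of 100 drawn splits, the real one, called as many as 6073 genes, with 295 in the highest other split. This lay under the 5 in 100 set beforehand, against a chance division if the samples are independent between conditions. The draws shuffled genotype separately in each condition, although same-numbered KO Th0 and KO Th1 samples deviated together. If a number marks the same animal in several conditions, these splits cannot decide the question. In the comparisons of 2 groups the 10 splits were too few: the highest other split called 1 gene in Th0, 5 in Th1, 215 in Th2 and 22 in Th17, and 0 in WT Th0 against naive, 3 in WT Th1, 7 in WT Th2, 0 in WT Th17 and 6 in WT Treg against Th0, each with 1 split, the real one, at the real count. In naive cells 2 of the 10 splits reached the real count of 150, with 401 in the other, which set WT naive 1, WT naive 2 and KO naive 2 against the rest. In Treg 2 of 10 reached 552, with 895 in the other, which set WT Treg 1, KO Treg 1 and KO Treg 2 against the rest, while Trim28 at 6.21 in KO Treg 3 and 9.53 in WT Treg 1 did not speak for exchanged labels.

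Known lineage genes in their own lineage were mixed. Ifng (-2.18) and Eomes (-2.55) in Th1 and Il13 (-1.41) in Th2 were lower, as was Il17a (-0.62) in Th17, whose call was lost in 7 settings. Ifng was uneven between the KO Th1 samples (SD 1.93) and did not pass in a fit to the Th1 samples alone. Tbx21 (-0.52) in Th1, Gata3 (0.10) in Th2, Il17f (-0.30) in Th17 and Foxp3 (-0.15) in Treg did not pass. The signature of a lineage was not tested in KO cells of that lineage.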
